A study of Culex pipiens pallens and Culex quinquefasciatus with 12 samples.

How the data were processed

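Gene expression was measured in 12 libraries of whole mosquito larvae, 5 from *Culex pipiens quinquefasciatus* and 7 from *Culex pipiens pallens*. Per the labels' protocols, total RNA of 30 larvae per library was pooled, poly(A) RNA was isolated, and libraries that do not record the strand were sequenced on an Illumina instrument. The authors deposited 1 table per library. Per the file headers it holds, for each gene model, the count of uniquely mapped reads, the length, the percent of the model covered by reads, and an RPKM value. The deposited RPKM values equalled the counts divided by length and library total, to rounding error. In all 12 libraries the counts summed to the total in the header. The deposited coverage percent was used only to compare the breadth of coverage between the subspecies. The aligner, the counter, their versions and the name of the genome build are not given in the sources used here. Gene models carry identifiers beginning with CPIJ and coordinates on scaffolds named supercont3, which are given as in the files. The files give no exons, so positions refer to whole gene models; 89.24% of the lengths were multiples of 3, so lengths are mostly coding lengths.

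Genes without reads are left out of a library's table and were set to 0. Descriptions came from the files themselves; 7516 of 17757 gene models were described only as hypothetical or predicted, or had no description, and 138 were not protein coding. None of the identifiers matched the RefSeq gene table at hand (0 matches), which belongs to another assembly and was not used here. Names of P450 genes are those of the description and follow similarity to other species. Only unique reads were counted, which takes reads from any near-identical copies, and sequence differences between the subspecies and the reference were not analysed here. Without strand, reads of overlapping or antisense genes cannot be told apart.

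The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the counts as deposited, with TMM normalization, filterByExpr, robust dispersion and the contrast pallens minus quinquefasciatus over all 12 libraries, which left 10617 genes. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. CPM values are TMM-normalized, and means are given with the SD over 7 pallens or 5 quinquefasciatus libraries. The biological coefficient of variation was 42.0%. The median log2 change of all tested genes was 0.02. A count of 3 reads, the limit that a count of 0 allows, corresponded to 0.579 to 0.772 CPM by library totals alone, without TMM. TMM-normalized values can lie outside this range: 3 reads of ankyrin3 in quinquefasciatus 5 were 0.790 CPM. The test was tested on simulated data made for this comparison over 10617 genes: 15 of 100 genes changed 2-fold and 87 of 100 changed 4-fold were recovered, with 2 false calls among 104, so many changes near 2-fold would be missed. The simulated genes varied independently, with no structure shared among libraries. The number of false calls therefore may not hold for the real libraries.

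Before the data were examined, 27 gene lists were fixed by words in the descriptions, as were the tests, the alternatives and the rule for named genes. Lists with at least 5 tested members were tested with camera of limma 3.58.1 with an estimated correlation between genes, two-sided, adjusted over 26 lists; a preset correlation of 0.01 and fry were alternatives. In simulated data over 10617 genes, a list of 60 genes raised 1.5-fold was called (camera adjusted p = 2.27e-06) and 0 other lists were. The simulated genes varied independently, whereas the estimated correlation in the real lists reached 0.763 (cytosolic ribosomal proteins). The simulation thus does not show what shift would be called in a list of correlated genes. Calls within a list were also counted with p adjusted over the list alone. The spread of a list was the median SD of log2(CPM + 1) within a subspecies, ranked among 10000 random lists matched in 20 expression bins. List means were also compared by an exact permutation test over 792 splits of the libraries, a test added after the data were seen. No paired analysis was made, because replicate numbers were given in accession order and pair no libraries. The rule for named genes took the 8 largest changes each way among described, called, non-overlapping genes with a mean log2 CPM of at least 3; the 2 smallest p of 7 lists and of any other list called; and the 6 described genes with the largest SD within a subspecies and a mean log2 CPM of at least 5.

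Alternatives were other normalizations, other filters on low counts, DESeq2 1.42.0, limma-voom, limma on log2 RPKM with 3 pseudocounts, stricter thresholds and each library left out in turn. Added after the data were seen were 2 surrogate variables from sva 3.50.0, the mean of the cuticle or the digestive protease list as a covariate, the summing of close pallens pairs, and leaving out pallens 6 and 7 together. For exchanged labels, a first test used genes called from the other 10 libraries and did not decide; a test on genes nearly without reads in quinquefasciatus 1 to 4 took its place after the values were seen. A test of sequencing depth as the reason why pallens 1 and quinquefasciatus 5 stand apart was dropped after it had argued against depth, since neither was among the libraries with the fewest reads, and the bound for moulting state was restated on a bootstrap interval, which left its outcome as it was. Breadth of coverage at equal reads per base was modelled with mgcv 1.9.3. Tables were read with pandas 2.3.3 and figures drawn with matplotlib 3.10.9 in Python 3.11.15. Resistance levels were not analysed here, since no label ties one to a library.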

Results

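The series measured gene expression in larvae of the common house mosquito, in 2 subspecies of the *Culex pipiens* complex: *Culex pipiens quinquefasciatus*, the southern house mosquito of warm regions, and *Culex pipiens pallens*, the northern house mosquito of East Asia. Each library was made from poly(A) RNA of a pool of 30 larvae, and there were 5 quinquefasciatus libraries and 7 pallens libraries. The title of the series speaks of different levels of resistance, but the labels give no level for any library, so subspecies was the only factor compared. Unique reads on gene models ranged from 4.4e6 to 5.2e6 per quinquefasciatus library and from 3.9e6 to 4.9e6 per pallens library. Between 14321 and 15467 gene models had at least 1 read in a library, and 11979 of 17757 were read in all 12. The most abundant transcript was that of arylphorin subunit C223 (CPIJ009033-RA), a larval storage protein, with a mean of 4.13% of all reads. No pair of libraries was as alike as repeated sequencing of 1 library would be: the smallest chi-square per degree of freedom between any pair was 17.0, between pallens 6 and pallens 7.

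The comparison of the subspecies asked which transcripts differed between pallens and quinquefasciatus larvae. Among families known from detoxification, 8 cytochrome P450 genes, 2 carboxylesterase genes and 1 glutathione S-transferase gene were lower in pallens larvae, and no member of these 3 families was higher at the threshold over all genes. Of these families only the P450 list was called as a whole. An opsin and a chitinase-like gene were among the genes higher in pallens larvae. Among 10617 genes tested, 57 differed at an adjusted p under 0.05 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), of which 36 were higher and 21 lower in pallens. Of the 57, 21 were described only as hypothetical proteins. At an unadjusted p under 0.05 there were 1382 genes, where chance would give 530.85. In 51 of the 57 the libraries of the subspecies did not overlap; over all tested genes this held for 130, or 1.22%, against 0.253% by chance. That chance share is a mean over splits and gives no spread. Exchanging the labels of pallens 1 and quinquefasciatus 5 gave 173 such genes. The 34 other exchanges of 1 library each way gave 7 to 269, so 130 alone does not set the subspecies apart. The number of calls rested on single libraries: it was 229 without pallens 1, of which 80 were higher and 149 lower, so that the majority turned, and 209 without quinquefasciatus 5, and it fell to between 9 and 33 without any other library. At the genes called without it and also tested over all 12 libraries, quinquefasciatus 5 lay nearer its own subspecies at only 32.3% of 201 and pallens 1 at only 31.0% of 229, whereas each of the other 10 libraries did so at 75.8% or more of its own 9 to 33 such genes. These shares largely restate the change in calls and are not separate evidence. Only 56 of the 229 genes called without pallens 1, and 57 of the 209 without quinquefasciatus 5, were also called over all 12 libraries. Without pallens 4 this held for 29 of 33, and without quinquefasciatus 1 for 9 of 9. With both left out 366 genes were called, and at the 353 of them tested over all 12 libraries the shares were 47.6% for quinquefasciatus 5 and 53.0% for pallens 1. No label says that the pools came from separate strains or cultures, so p-values measure only the spread between these samples, which includes any resistance levels that the labels leave out.

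Cytochrome P450s are the oxidases with which insects metabolise many insecticides and plant compounds, and they were the gene family that differed most clearly. Of 115 P450 genes tested, 8 fell and 0 rose in pallens over all genes, and 36 were lower and 4 higher when adjusted over the list alone. Fold changes were negative in 82 of the 115, with a median log2 change of -0.57. The list as a whole was lower in pallens (camera with an estimated correlation, adjusted p = 0.0315; adjusted p = 1.98e-14 with a preset correlation of 0.01). The mean of the list was 3.93 ± 0.20 log2(CPM + 1) in pallens (SD, n = 7) and 4.49 ± 0.11 in quinquefasciatus (SD, n = 5), with no overlap (adjusted p = 0.0328 over 26 lists, exact permutation test in both directions, added after the values were seen; the raw p of 0.00126 is the smallest these splits can give). The gene with the smallest p was CPIJ016854-RA, described only as cytochrome P450, on scaffold supercont3.869 at 123548 to 125083. It averaged 3.14 ± 1.04 CPM in pallens (n = 7) and 12.7 ± 3.50 CPM in quinquefasciatus (n = 5), 3.99-fold lower in pallens (SE 0.28 on the log2 scale, edgeR adjusted p = 0.0114). On the same scaffold, at 111560 to 113138, P450 6a9 (CPIJ016850-RA) averaged 13.2 CPM against 35.8 CPM, a log2 change of -1.44. P450 17A1 (CPIJ010537-RA) and P450 9b2 (CPIJ010540-RA) lay together on supercont3.278, and their log2 changes were -1.14 (SE 0.19) and -1.38 (SE 0.25). P450 4c21 (CPIJ001759-RA) fell by 1.44 on the log2 scale and P450 6j1 (CPIJ002535-RA) fell by 1.75. These 6 genes had no overlap between the subspecies. The remaining pair, P450 71B38 (CPIJ005954-RA) and P450 82A2 (CPIJ005958-RA), named after their values were seen, lay on supercont3.104 and did overlap: P450 82A2 ranged from 133 to 371 CPM in quinquefasciatus 1 to 4, but quinquefasciatus 5 had 15.8 CPM, among the pallens values of 11.6 to 31.1 CPM. The 4 P450 genes higher in pallens when adjusted over the list alone, also named after their values were seen, were Cyp49a1 (CPIJ000067-RA), P450 98A1 (CPIJ010229-RA), P450 3A19 (CPIJ010548-RA) and CPIJ019703-RA, with log2 changes of 0.94, 1.35, 1.15 and 1.28. The digestive protease list also had a lower mean in pallens (4.88 ± 0.39 against 5.33 ± 0.26 log2(CPM + 1)), and the P450 list was no longer called with that mean as a covariate (adjusted p = 0.0745), nor without quinquefasciatus 2 (0.112), quinquefasciatus 5 (0.0944), pallens 4 (0.0644) or pallens 7 (0.0557), nor with 2 surrogate variables (0.126) or with pallens 6 and 7 both left out (0.105). The list median was -0.34 with the protease covariate and -0.45 with surrogate variables. It was -0.62 without quinquefasciatus 2, -0.56 without quinquefasciatus 5, -0.62 without pallens 4, -0.61 without pallens 7 and -0.60 without pallens 6 and 7. The 8 P450 calls became 2 to 22 with 1 library left out and 0 with pallens 6 and 7 left out. The 36 lower and 4 higher over the list alone became 20 to 50 and 0 to 8 with 1 library left out. Only reads that mapped uniquely were counted, and how alike the P450 sequences are was not analysed here.

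**Figure D1:**
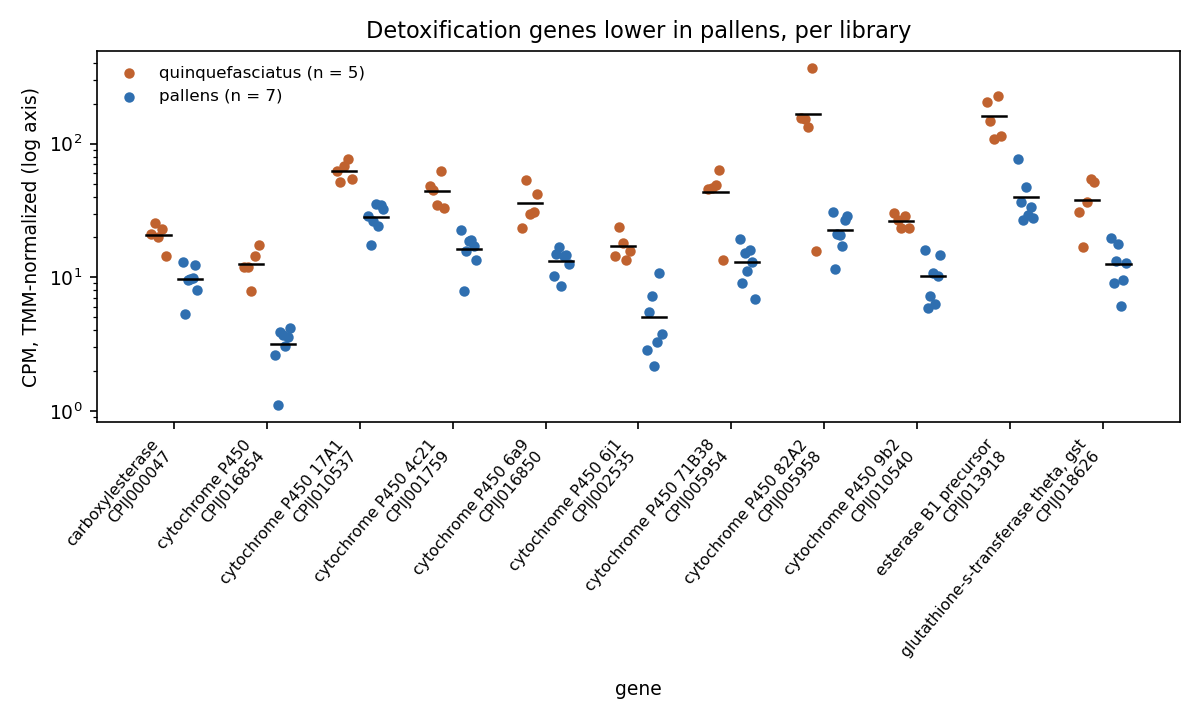
Normalized CPM (log axis) of the 11 detoxification genes called lower in pallens, 1 point per library, with black lines at the group means (quinquefasciatus n = 5, pallens n = 7). In P450 82A2 the 5th quinquefasciatus library lies at 15.8 CPM, among the pallens libraries.

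Carboxylesterases hydrolyse ester insecticides, and the one with the smallest p was esterase B1 (CPIJ013918-RA), the esterase known from organophosphate resistance in *Culex*. It lay on supercont3.512 at 34360 to 36454 and averaged 39.8 ± 17.8 CPM in pallens (n = 7) and 161 ± 54.3 CPM in quinquefasciatus (n = 5). The quinquefasciatus mean was 4.04 times the pallens mean (edgeR adjusted p = 0.0149). Within pallens it ranged from 26.8 to 76.8 CPM and within quinquefasciatus from 108 to 229 CPM. A second carboxylesterase (CPIJ000047-RA) fell to 9.72 ± 2.62 CPM from 20.8 ± 4.14 CPM (edgeR adjusted p = 0.0402), a call kept in 12 of 27 alternatives. Over the family, 2 of 27 tested genes fell and 0 rose, and 2 were lower when adjusted over the list alone; the list as a whole was not called (adjusted p = 0.289 with an estimated correlation, 0.00302 with a preset one). Of 30 glutathione S-transferase genes, which couple glutathione to reactive compounds, 1 fell over all genes and 3 were lower when adjusted over the list alone. The gene that fell was the theta-class CPIJ018626-RA, at 12.6 ± 4.90 CPM in pallens and 38.2 ± 15.6 CPM in quinquefasciatus (edgeR adjusted p = 0.0447), a call also kept in 12 of 27 alternatives. Its neighbour on supercont3.1224, glutathione S-transferase 1-1 (CPIJ018627-RA), averaged 120 ± 34.0 and 260 ± 71.9 CPM and missed the threshold over all genes (edgeR adjusted p = 0.0693). The third, named after its values were seen, was CPIJ014051-RA, with a log2 change of -1.38. The glutathione S-transferase list was not called (adjusted p = 0.665 with an estimated correlation). The UDP-glycosyltransferases, which attach sugars to such compounds, had 0 calls among 21 genes, although 15 had negative fold changes and the median was -0.75 (camera adjusted p = 0.286 with an estimated correlation, 0.000329 with a preset one). Of 45 ABC transporter genes, which pump compounds out of cells, 0 differed and the median log2 change was -0.06 (camera adjusted p = 0.765).

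Proteins that insecticides bind in the nervous system did not separate the subspecies. Of 12 tested genes for sodium channel, acetylcholinesterase and receptor subunits, 0 passed the threshold over all genes or adjusted over the list alone, while 10 had positive fold changes. The list had a median log2 change of 0.42, and its call with a preset correlation (adjusted p = 0.0243) was lost with an estimated one (adjusted p = 0.286). The acetylcholinesterase fragment CPIJ006034-RA averaged 3.66 ± 0.72 CPM in pallens and 2.17 ± 0.75 CPM in quinquefasciatus (edgeR adjusted p = 0.24). A nicotinic acetylcholine receptor subunit, CPIJ015652-RA, averaged 2.44 ± 1.08 and 1.10 ± 0.97 CPM (edgeR adjusted p = 0.368). These genes had only 2 to 19 reads per library.

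Serine proteases of the gut digest protein in the food. Of 61 digestive serine protease genes, 0 passed the threshold over all genes and 2 were lower in pallens when adjusted over the list alone. Fold changes were negative in 44 of the 61, with a median of -0.42, and the list was called with a preset correlation (adjusted p = 1.75e-05) and not with an estimated one (adjusted p = 0.308). The 2 genes, HzC4 chymotrypsinogen (CPIJ002139-RA) and chymotrypsin-1 (CPIJ002126-RA), lay on supercont3.21. The first averaged 107 ± 33.2 CPM in pallens and 234 ± 34.0 CPM in quinquefasciatus (edgeR adjusted p = 0.0534). The second averaged 15.1 ± 9.78 and 50.4 ± 26.2 CPM (edgeR adjusted p = 0.0911). Next to the first on the scaffold, at 1135472 to 1136681, a gene outside the list that is described as serine proteases 1/2 (CPIJ002141-RA) fell from 343 ± 138 CPM in quinquefasciatus to 86.1 ± 50.5 CPM in pallens (edgeR adjusted p = 0.0404). Trehalase (CPIJ017949-RA), which splits the blood sugar of insects, fell from 51.1 ± 14.2 to 20.2 ± 7.06 CPM (edgeR adjusted p = 0.0345). The calls of trehalase and of CPIJ002141-RA were each kept in only 14 of 27 alternatives.

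Genes higher in pallens were led by opsin-1 (CPIJ004067-RA), a light receptor of photoreceptor cells, on supercont3.60 at 303692 to 304879. It averaged 39.1 ± 40.9 CPM in pallens (n = 7) and 2.52 ± 0.86 CPM in quinquefasciatus (n = 5), a log2 change of 3.96 (SE 0.78, edgeR adjusted p = 0.0412), and its SD in pallens was as large as its mean. Pallens 7 (119 CPM) and pallens 6 (68.7 CPM) carried that mean, while pallens 1 was at 3.92 CPM, and the gene was not called without either pallens 6 or pallens 7. Chitotriosidase-1 (CPIJ019120-RA), of the chitinase family, was more even: 74.8 ± 12.8 CPM in pallens and 23.7 ± 6.02 CPM in quinquefasciatus, 3.15-fold higher (edgeR adjusted p = 0.00937). H/ACA ribonucleoprotein complex subunit 4 (CPIJ006466-RA), which modifies ribosomal RNA, rose 5.32-fold to 15.1 ± 5.89 CPM. The FACT complex subunit Ssrp1 (CPIJ020011-RA), a histone chaperone, rose 3.41-fold to 24.0 ± 7.86 CPM. Eukaryotic translation initiation factor 2C 2 (CPIJ006138-RA), an Argonaute protein of RNA silencing, rose 3.01-fold to 21.2 ± 7.25 CPM. The mitochondrial 28S ribosomal protein S22 (CPIJ007012-RA) rose 2.20-fold to a mean of 23.1 CPM. Ankyrin3 (CPIJ017154-RA) and a putative serine/threonine kinase (CPIJ019986-RA) rose 6.14-fold and 5.41-fold. These 8 genes were chosen by size of change and not as a pathway.

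Lists of structural, stage and tissue genes gave few calls. Of 76 cuticle protein genes, 0 passed the threshold over all genes or adjusted over the list alone, although 61 had positive fold changes, with a median of 1.27 (camera adjusted p = 0.521 with an estimated correlation, 0.000225 with a preset one). The 2 with the smallest p were CPIJ001839-RA, at 63.7 ± 62.7 CPM in pallens and 7.26 ± 7.19 CPM in quinquefasciatus, and cuticle protein 18.6 (CPIJ013765-RA), at 13.5 ± 14.6 and 1.30 ± 1.30 CPM. Of 12 larval storage protein genes, 0 passed (camera adjusted p = 0.765): larval serum protein 1 beta chain (CPIJ006538-RA) averaged 135 ± 96.9 CPM in pallens and 360 ± 231 CPM in quinquefasciatus, and larval serum protein 2 (CPIJ009032-RA) averaged 1131 ± 915 and 2697 ± 1897 CPM. Of 83 cytosolic ribosomal protein genes, 78 had positive fold changes with a median of 0.32, and only 40S ribosomal protein S10 (CPIJ007531-RA), at 3.53 against 1.16 CPM, was higher (camera adjusted p = 0.665 with an estimated correlation, 6.74e-07 with a preset one). In the phototransduction list of 25 genes only opsin-1 rose over all genes, and a second opsin-1 model (CPIJ012052-RA) was higher when adjusted over the list alone (camera adjusted p = 0.308). In the muscle list of 60 genes 1 actin (CPIJ016054-RA) rose, at 3.92 against 1.15 CPM (camera adjusted p = 0.79). The testis list of 22 genes had 0 calls and a median of 0.59 (camera adjusted p = 0.49), and its mean was 3.62 ± 0.51 log2(CPM + 1) in pallens and 3.16 ± 0.32 in quinquefasciatus.

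The remaining lists gave 0 calls over all genes in the edgeR test. Adjusted over the list alone, 1 gene was lower in pallens in each of 3 lists: 71 immune genes (a galactose-specific C-type lectin, CPIJ012307-RA), 71 respiratory chain genes (a putative NADH:ubiquinone dehydrogenase, CPIJ016783-RA) and 44 lipase genes (salivary lipase, CPIJ005463-RA). The same lipase and a salivary angiopoietin (CPIJ017657-RA) were lower among 31 salivary and adult female genes, and 1 of 41 proteasome genes was higher (subunit beta type 3, CPIJ016158-RA). These single genes were named after their values were seen. No gene passed in either way among 41 heat shock and chaperone genes, 23 of chitin metabolism, 17 of odorant binding, 22 of histones and DNA replication, 43 of fatty acid and cuticular lipid synthesis, 26 of juvenile hormone and ecdysone, 13 of the vacuolar ATPase and 25 antioxidant genes. Chitotriosidase-1 (CPIJ019120-RA), called above, was outside the chitin metabolism list, because its description lacks the words that define the list. Camera with an estimated correlation gave adjusted p of 0.286 for the immune list, 0.937 for the respiratory chain, 0.665 for lipases, 0.308 for salivary and adult female genes, 0.797 for the proteasome, 0.308 for heat shock genes, 0.937 for chitin metabolism, 0.79 for odorant binding and for histones, 0.665 for lipid synthesis, 0.49 for juvenile hormone and ecdysone, 0.797 for the vacuolar ATPase and 0.937 for antioxidants. With a preset correlation 6 further lists were called that the estimated one did not call: testis (adjusted p = 0.00815), juvenile hormone and ecdysone (0.0175), heat shock (0.0238), phototransduction (0.0292), immune (0.0295) and salivary and adult female genes (0.0295). Only 3 transposon gene models matched and 0 had enough reads to test.

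The second question was how far libraries of one subspecies differed among themselves. Cuticle genes varied most: the median SD within a subspecies was 1.67 on the log2(CPM + 1) scale, where random lists of equal expression gave 0.417. Larval storage proteins (1.49 against 0.431), carboxylesterases (0.797 against 0.418), UDP-glycosyltransferases (0.709 against 0.410), digestive serine proteases (0.690 against 0.411), glutathione S-transferases (0.686 against 0.406) and P450s (0.651 against 0.406) also varied more than random lists. In all, 18 of 26 lists lay above the 95th percentile of 10000 random lists, while cytosolic ribosomal proteins (0.354) and the proteasome (0.344) lay at percentiles 0 and 1.81. Insecticide targets (0.453 against 0.454) lay at percentile 49.5. The most variable described genes had very wide ranges. Fatty acyl-CoA reductase 1 (CPIJ004391-RA), an enzyme of long-chain alcohol and wax synthesis, ranged from 0.222 to 1034 CPM. Cuticle protein CPIJ001836-RA ranged from 3.47 to 1914 CPM, and larval cuticle protein A3A (CPIJ001830-RA), on the same scaffold, from 1.07 to 985 CPM. Cuticle protein 18.6 (CPIJ013795-RA) ranged from 0.53 to 1546 CPM and its neighbour CPIJ013794-RA from 0.790 to 651 CPM. Trypsin 5 (CPIJ013616-RA) was at 1326 CPM in quinquefasciatus 3 and 1203 CPM in pallens 3 and at 89.8 CPM or less in the other 10 libraries.

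**Figure D2:**
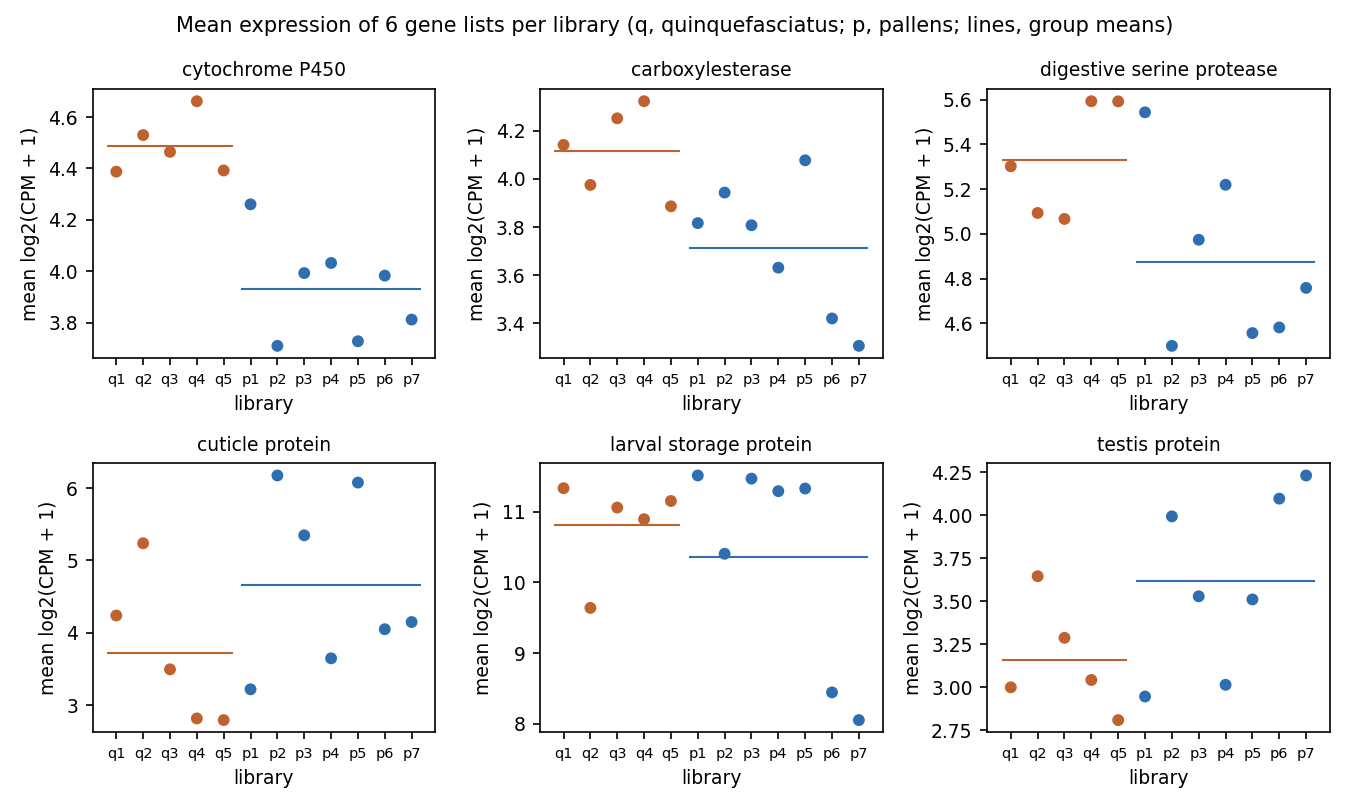
Mean log2(CPM + 1) of 6 gene lists in each library (q, quinquefasciatus, n = 5; p, pallens, n = 7), with lines at the group means. The P450 means of the subspecies do not overlap, whereas cuticle means run from 2.79 to 6.17 across libraries of both.

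Cuticle list means were highest in pallens 2 (6.17) and pallens 5 (6.08) and lowest in quinquefasciatus 5 (2.79) and quinquefasciatus 4 (2.81), with overlap between the subspecies (quinquefasciatus 2 at 5.24, pallens 1 at 3.22). Storage protein means were 8.45 and 8.05 in pallens 6 and 7 and between 9.64 and 11.5 in the other 10 libraries. Pallens 6 and 7 also had the highest testis (4.10 and 4.23) and phototransduction means (5.0 and 5.1). The closest pairs of libraries were pallens 6 with 7 (Spearman rho 0.961) and pallens 2 with 5 (rho 0.950). Mean rho was 0.891 within and 0.876 between subspecies, a difference of 0.0154 that did not pass the exact one-sided permutation test over all splits (p = 0.0606); it did pass without pallens 1 (0.0284, p = 0.0108) or without pallens 4 (0.0213, p = 0.0368). The first 3 principal components held 36.1%, 18.9% and 11.6% of the variance. On the third, quinquefasciatus 1 to 4 scored between 23.5 and 38.0, while quinquefasciatus 5 scored -26.5 and the pallens libraries between -29.2 and 2.30.

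**Figure D3:**
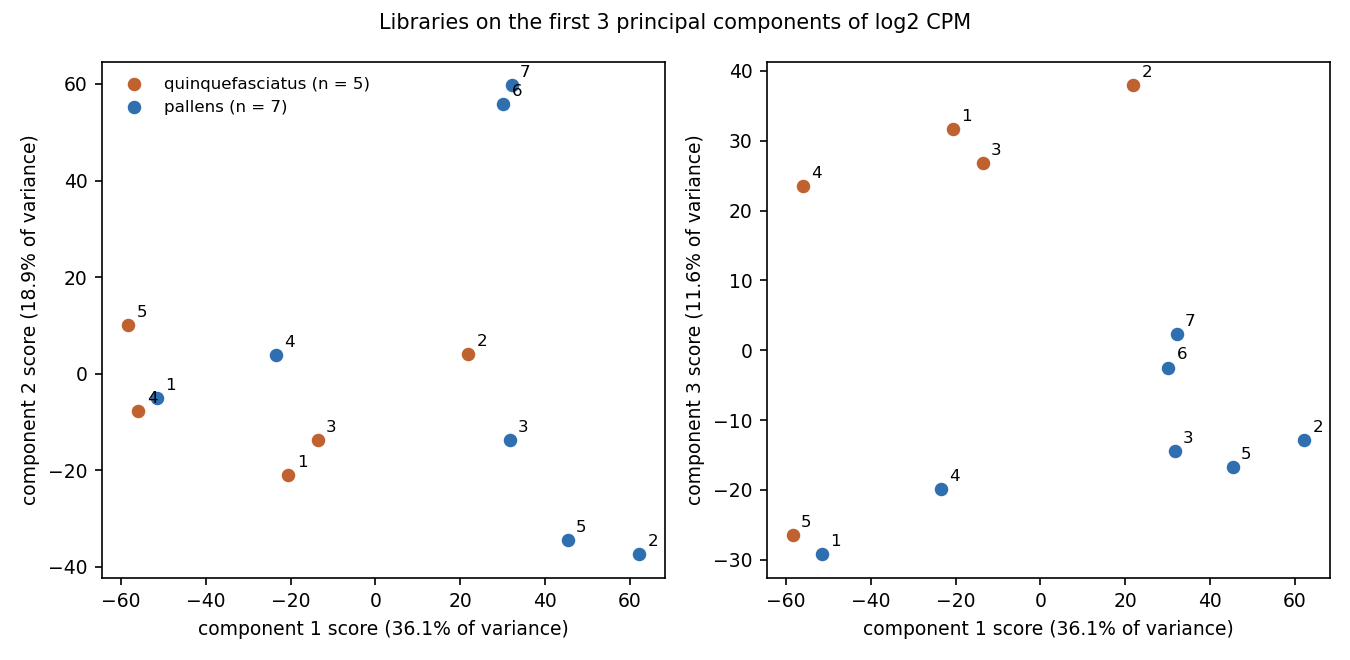
Libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM, 1 numbered point per library, coloured by subspecies (quinquefasciatus n = 5, pallens n = 7). Component 3 sets quinquefasciatus 1 to 4 apart from the rest, with quinquefasciatus 5 among pallens.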

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

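The tests of moulting and feeding state, of wrong labels, of males, of gene placement and of other splits for the 57 calls were chosen only after the results they bear on were seen, the test of exchanged labels in place of an earlier one that did not decide; the tests of coverage breadth and of other splits for the P450 genes were set before.

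The first pattern was the lower P450 expression of pallens, with 8 calls and a lower list. Reads of pallens mapping poorly to diverged parts of these genes would leave gaps, but at equal reads per base the breadth of coverage of the 36 genes lower by list differed by a median of -0.7265 percentage points (95% bootstrap interval over genes -2.67 to 0.686), well above the -5 set as the bound, so gaps of that size were not seen; an even loss of reads over a whole gene was not tested. For pools at different moulting stages, with the cuticle list mean as a covariate the list median was -0.4534 (95% interval over genes -0.677 to -0.218). Without the covariate it was -0.57 (interval -0.848 to -0.326). The list was still called, narrowly (camera adjusted p = 0.0494). The part of moulting stage that this mean captures thus does not account for the whole difference. The mean is a rough measure of stage, and the interval treats genes that vary together as separate. Moulting stage is therefore not excluded. Feeding or gut share stays open: with the digestive protease mean as a covariate the median was -0.3362 (interval -0.569 to -0.209), and the call ended as the median shrank (adjusted p = 0.0745), while the 2 means may themselves differ by subspecies. Of 100 splits of the libraries only 1, the real one, gave 8 or more lower in the group of 7, the highest other being 1, but the split of pallens 2, 3, 5, 6 and 7 against the rest gave 24 lower in those 5 pallens libraries, and a subspecies difference or a difference of resistance level stays open and untested.

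The second pattern was that leaving out pallens 1 or quinquefasciatus 5 raised the number of calls from 57 to 229 or 209. At the genes called without it and also tested over all 12 libraries, quinquefasciatus 5 lay nearer its own subspecies at 32.3% of 201, pallens 1 at 31.0% of 229 and each other library at 75.8% or more of its own 9 to 33 genes. These shares largely restate the pattern, since only 57 of the 209 and 56 of the 229 genes were also called over all 12 libraries. At 353 of the 366 genes called with both left out (those tested over all 12), the shares were 47.6% for quinquefasciatus 5 and 53.0% for pallens 1. The other libraries have no such value. For an exchange of the 2 labels the earlier test, on those 353 genes, did not decide. Exchanging them gave 73 calls against 57 (6 called both ways) and 173 genes without overlap against 130 (7 to 269 in 34 other exchanges). The later test used 9 genes with at most 1 read in each of quinquefasciatus 1 to 4 and at least 5 in each of pallens 2 to 7. Pallens 1 had at least 5 reads at 77.78% of them and at most 1 at 0. Quinquefasciatus 5 had reads at most of them as well. If such genes marked the subspecies, an exchange would leave pallens 1 out of place. The labels as given would then leave quinquefasciatus 5 out of place, so this test cannot decide on an exchange. A wrong label on quinquefasciatus 5 alone is a candidate explanation for its own part of the pattern, and does not address pallens 1. Of 7 such genes read in all pallens libraries, quinquefasciatus 5 had at least 5 reads at 71.43% and at most 1 at 0. A quinquefasciatus stock of another origin or mixed descent could do the same. The P450 list mean of quinquefasciatus 5, 4.39, lay with quinquefasciatus 1 to 4 (4.39 to 4.66), above the highest pallens mean of 4.26. Moving this library to pallens gave 194 calls, and moving pallens 1 to quinquefasciatus gave 333. Pools with fewer or younger males are another candidate explanation, for the likeness of quinquefasciatus 5 and pallens 1. In the testis list these libraries held ranks 1 and 2 from the bottom, with means of 2.81 and 2.95. The next was close at 3.0, and only 22 of the list's 40 genes were tested. Shared extremes were not particular to the testis list. Quinquefasciatus 5 and pallens 1 also had the highest vacuolar ATPase means of the 12 libraries (7.70 and 7.81). The same held for the respiratory chain (7.30 and 7.42) and ABC transporter lists (4.62 and 4.57). The testis ranks thus do not single out males as the reason for the likeness.

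The third pattern was that 14 of the 57 called genes lay within 50 kb of another called gene. Chance placement gave 0 to 5 in the central range of 10000 random sets and 11 at most, so 14 is beyond it. Copies of one family side by side are a candidate explanation for 4 of the 7 neighbouring pairs (57.14%), which shared a list or a description. Of these, 3 were P450 pairs, already part of the first pattern, and 1 was a pair of serine proteases 1/2 genes. The remaining pairs, such as actin with a NEDD8-activating enzyme subunit, shared neither, so this explanation does not reach them. All 7 pairs changed in the same direction. Whether neighbours share regulation or share reads was not tested.

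For the 57 calls as a whole, 3 of 100 splits of the libraries into 5 and 7, the real one included, gave as many, so a count of 57 was uncommon but not unique to the subspecies. The highest other split, pallens 2, 3, 5, 6 and 7 against the rest, gave 702 calls, the same split that gave 24 P450 genes, which points to a structure of the samples that crosses the subspecies; 96 of the 99 other splits gave 0.

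Single libraries far from the others of their subspecies were found in 12 of 126 groups of values, where chance flags about 5%. The groups include the genes named for the largest SD within a subspecies, where outlying values are built in by the choice. Flags for fatty acyl-CoA reductase 1, cuticle protein CPIJ001836-RA, larval cuticle protein A3A and trypsin 5 are of this kind. The count of 12 therefore cannot show an excess over chance. In pallens 4, H/ACA ribonucleoprotein complex subunit 4 (CPIJ006466-RA) was at 27.3 CPM (others 9.12 to 15.2) and chymotrypsin-1 (CPIJ002126-RA) at 36.18 CPM (others 7.68 to 17.5). In pallens 1, esterase B1 (CPIJ013918-RA) was at 76.76 CPM (others 26.8 to 47.7) and the UDP-glycosyltransferase list had a mean of 4.503 log2(CPM + 1) (others 3.43 to 3.73). In pallens 3, fatty acyl-CoA reductase 1 (CPIJ004391-RA) was at 1034 CPM (others up to 440) and trypsin 5 (CPIJ013616-RA) at 1203 CPM (others up to 89.8). In quinquefasciatus 3, trypsin 5 was at 1326 CPM (others up to 31.3). In quinquefasciatus 2, the receptor subunit CPIJ015652-RA was at 2.753 CPM (others up to 1.05), cuticle protein CPIJ001836-RA at 1857 CPM (others up to 435), larval cuticle protein A3A (CPIJ001830-RA) at 628.1 CPM (others up to 83.4), and the storage protein list had a mean of 9.639 (others 10.9 to 11.3). In quinquefasciatus 1, HzC4 chymotrypsinogen (CPIJ002139-RA) was at 173.9 CPM (others 240 to 258).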

How the results depend on the processing

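The covariate, summed-pair and paired leave-out settings were chosen after the data were seen; the others were planned. No paired analysis was possible because replicate numbers were given in accession order and pair no libraries. None of the 28 named genes put through the alternatives changed sign; genes named for their spread or after their values were seen were not put through them. The 57 called genes kept their sign wherever they were tested. RLE (57 calls), upper-quartile (51), library totals (73), no filter (64) and surrogate variables (76) stayed within 1.5 times the count. The genes were not all the same: of the 57 called genes, 57, 51, 51, 51 and 38 were called again in these settings, in that order. Other settings did not, as follows for calls, higher and lower: DESeq2 gave 295, 162 and 133; limma-voom 92 with 62 higher; limma on log2 RPKM 136, 92 and 44 with a pseudocount of 1, 135, 94 and 41 with 0.1, and 91 with 63 higher with 0.01; at least 10 reads in every library 27 with 12 higher, with 31 of the 57 still tested; an adjusted p under 0.01 left 2, 2 and 0. The cuticle covariate gave 18, 11 and 7; the protease covariate 11, 8 and 3; pallens pairs summed 11, 8 and 3; pallens 6 and 7 left out together 5, 4 and 1; and 2 surrogate variables 36 lower. With a library left out in turn, calls ran from 9 to 229, higher from 5 to 139 and lower from 3 to 149; the low end came without quinquefasciatus 1 or 3 (9 each) and the high end without pallens 1, where the majority turned to lower (80 higher, 149 lower).

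P450 genes lower numbered 20 with DESeq2, 4 with the cuticle covariate, 2 with the protease covariate, 2 with pairs summed, 0 without pallens 6 and 7 and 2 to 22 with a library left out. Adjusted over the list alone, the 36 lower became 24 with the cuticle covariate, 16 with the protease covariate, 18 with pairs summed, 26 without pallens 6 and 7, and 20 (without quinquefasciatus 4) to 50 (without pallens 1) with a library left out. The adjusted p of the P450 list was 0.1264 with surrogate variables, 0.07452 with the protease covariate and 0.1051 without pallens 6 and 7, each with 0 lists called, and 0.01051 to 0.1117 with a library left out (0 to 2 lists; the second was the UDP-glycosyltransferases without pallens 1). The preset correlation called 13 lists and fry 1. The difference in similarity ran from 0.007716 to 0.02836 with a library left out. The number of lists with a wide spread was 17 or 18 throughout. Of single named genes, chitotriosidase-1 was called in all 27 alternatives, H/ACA subunit 4 in 25 of 26, P450 6a9 in 25 and esterase B1 in 23 of 27, but opsin-1 in only 9 of 26, ankyrin3 in 12 of 26, the theta-class glutathione S-transferase CPIJ018626-RA and carboxylesterase CPIJ000047-RA in 12 of 27, P450 6j1 and initiation factor 2C 2 in 13, and trehalase and serine proteases 1/2 (CPIJ002141-RA) in 14. Over all 28 genes the alternatives left 553 outcomes on the same side of the threshold, moved 171 calls over it to weaker and 22 to stronger; the cause was not tested. Depth limits genes near 1 CPM, which rest on about 4 or 5 reads.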

Other observations

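All observations here, and the tests given with them, were chosen after the data were seen.

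Some genes were nearly silent in quinquefasciatus 1 to 4 and read in every other library. The clearest was a ferritin heavy chain gene (CPIJ014287-RA, supercont3.549 at 63417 to 63971), named for a subunit of an iron-storing protein. This gene had 0 to 1 reads in each of quinquefasciatus 1 to 4, 40 to 88 reads in each pallens library and 54 reads in quinquefasciatus 5. Tryptase-2 (CPIJ019165-RA) had 0 to 1, 13 to 58 and 24 reads in the same order. A short 60S ribosomal protein L7 model (CPIJ007287-RA) had 0, 8 to 23 and 9 reads. In all, 5 genes had at most 1 read in these 4 libraries and at least 5 in the other 8; over the other 494 choices of 4 libraries the highest count was 2, and 3 choices gave any. With quinquefasciatus 5 counted with its own subspecies, 0 genes met this rule in either direction.

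Pallens 1 and quinquefasciatus 5 listed the fewest gene models of the 12 libraries (14321 and 14338; the next was quinquefasciatus 4 with 14489). Of all pairs of libraries they shared the most gene models unlisted in both and listed in the other 10, with 68; the next pairs, each of them with quinquefasciatus 4, shared 27 and 26. No expected number was computed, and libraries with more unlisted genes share more of them by chance. Most of the 68 had no description, and no list was tested among them. Described ones included tubulin chains, a 33 kDa inner dynein arm light chain and a cytosol aminopeptidase (CPIJ000990-RA). They also included CPIJ012294-RA, described as a WD repeat-containing protein on Y chromosome (WD40 Y), at no more than 1.74 CPM. Others were receptors for GABA and glutamate, a pupal cuticle protein, a paired box protein, an Osiris protein, a glutathione S-transferase and a glucose dehydrogenase. The aminopeptidase, picked after its values were seen, was at 74.6 and 67.7 CPM in pallens 6 and 7, at 4.13 to 31.2 CPM in the other 8 libraries, and had 0 reads in pallens 1 and quinquefasciatus 5. Related genes CPIJ003539-RA and CPIJ009640-RA had 71.5 and 15.9 CPM in pallens 6 and at most 0.527 CPM in pallens 1 and quinquefasciatus 5.

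Moving 1 library at a time to the other subspecies gave 333 calls for pallens 1, 194 for quinquefasciatus 5 and 0 or 1 for each of the other 10. With quinquefasciatus 5 moved, 8 P450 genes were lower and 1 higher in pallens and the P450 list was not called (camera adjusted p = 0.291). With pallens 1 moved, 24 were lower and 1 higher (camera adjusted p = 0.011).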
